A study of Mus musculus with 46 samples.

How the data were processed

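The series holds 46 RNA samples in 22 groups, all from sorted cells of the mouse main olfactory epithelium. Of these, 18 were prepared with the SMARTer total RNA kit (6 stages of the neuronal lineage with 2 samples each, and 3 control and 3 Mex3a conditional knockout (cKO) samples of OMP-positive cells), 20 with the TruSeq total RNA kit (4 sorted stages and 6 transgene groups with 2 samples each), and 8 are the RNA counterpart of ribosome profiling. Per the labels, the globose basal cells of both kits and the precursor and late precursor cells of the SMARTer kit came from pups given tamoxifen at postnatal days 2 to 4 and sorted 48 h later, and the deletion was made with Foxg1-iresCre. No such treatment is given for the other stages. It therefore cannot be told apart from stage in globose against horizontal basal cells, or in Atf5 immature neurons against late precursors. The labels do not say that replicates are separate animals, so each p-value measures the spread between samples.

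The authors trimmed reads with cutadapt after FastQC, aligned them to mm10 with STAR and used DESeq2, per the processing notes in the labels. The stage, deletion and transgene tables hold raw counts of reads in the exons of 55487 genes, which per the file headers were made with featureCounts v2.0.2 in paired mode with no strand option, on Ensembl release 100 genes (GRCm38) and alignments filtered at quality 30. Counting without strand leaves antisense and overlapping genes uncertain, and olfactory receptors can share reads with near-identical paralogs. The deposited exon and intron tables hold counts per gene for the 4 OMP-driver libraries with Mex3a or GFP. The exon columns were checked and equal the matching columns of the transgene table, and the intron table covers 33041 genes. The deposited translation table gives, for each of the 4 groups of the ribosome profiling samples, 1 value of RNA counts in the coding sequence, footprint density in RPKM (reads per kilobase and 1e6 reads) and translation efficiency, which is a ratio of footprint to RNA density. It does not give the 2 samples of a group apart, so the edgeR tests planned for these samples could not be run. Its 12 remaining columns of values were not used.

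Counts per library came to between 25.7 and 39.5 M (1e6 counts) in the stage table, between 33.9 and 53.6 M in the deletion table and between 28.4 and 87.9 M in the transgene table. The RNA columns of the translation table held 27.8 (Ngn cKO), 89.3 (Ngn control), 26.9 (OMP cKO) and 31.9 (OMP control) M reads. Where a gene had no count in a group, the fold is given as a lower bound from a floor of 3 counts per library. These floors and the 95% Wilson intervals cover counting error only. Gene symbols were taken from GENCODE M21, which covers 55141 of the genes, and 99.8% of these lie on the same chromosome with the same start or end in both annotations.

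Each table was fitted with edgeR (quasi-likelihood F test, glmQLFit and glmQLFTest) after filterByExpr and TMM scaling, with all groups of the table in 1 fit and Benjamini-Hochberg adjustment over all genes tested, at an adjusted p of 0.05 with no fold threshold. CPM values (counts per 1e6 counts) use the TMM-scaled library sizes and are given as mean ± SD of the libraries of a group, and log2 folds with their standard errors (SE). The groups were compared along the lineage, transgene against GFP and Mex3a against its RING mutant within each driver, the Mex3a effect between drivers (an interaction term), and cKO against control. Exonic against intronic change was tested as the interaction of region and transgene with a term per library, on genes with a mean of at least 10 exonic and 10 intronic counts with each region's library size the sum of its counts kept and no TMM factor. In all, 30 gene lists (receptors, cell type markers, guidance and adhesion molecules, stress and RNA-handling genes) were written down before the data were examined. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and its members were also counted after edgeR's p-values were adjusted over the list alone. With a correlation estimated from the data, 16 of the 231 list calls held, and the p-value from that test stands beside each call that did not.

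The receptor share of a library is the percent of its gene counts on symbols of the form Olfr and a number. The effective number of receptor genes is the exponential of the Shannon entropy of receptor counts after thinning every library of a table to the same receptor total. Both were compared with exact two-sided permutation tests, whose smallest p is 0.333 for 2 against 2 libraries and 0.1 for 3 against 3. For the translation table, log2 ratios were taken for genes with at least 100 RNA reads in both groups, and each list's median was placed among those of 10000 random lists of the same size matched on expression in 10 bins.

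The text names genes by a rule set before the data were examined. For each comparison it takes Mex3a, the 6 genes per direction with the largest log2 fold among those past the threshold with no overlap between the groups' samples and a mean of at least 10 CPM in the higher group, up to 4 members of each list, and 3 receptors per direction with a mean of at least 1 CPM. The smallest folds were dropped first for length.

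The pipeline was tested on simulated data with 100 genes changed at each of both sizes, or 99 for the exonic minus intronic change. In the comparison of precursors with globose basal cells it recovered 7.0% of genes changed by 1 on the log2 scale and 64.0% of those changed by 2, with 5 false calls. For the Mex3a transgene the shares were 19.0% and 74.0% with 3 false calls, for the deletion 68.0% and 95.0% with 14, and for the exonic minus intronic change 26.3% and 79.8% with 4.

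Alternatives tried were DESeq2 and its size factors, no filter on low counts, a fit of only the compared groups, replicate numbers as a block, each library left out in turn, other settings of the receptor measures and of the exonic minus intronic test and, chosen after the data had been seen, the sustentacular marker level as a covariate, wild-type mature neurons as control, crossed replicate numbers and the founder of the Mex3a transgene. Per the labels the Mex3a libraries F1 and F2 come from founders with different insertion sites, so the spread between them includes that of the founders. Across the deletion libraries, deviations from the group mean correlated positively for all 3 same-numbered pairs of control and cKO (0.195, 0.191 and 0.182), a pairing read from the data and not stated in the labels. In the other comparisons with a block, same numbers correlated at 0.664 for INP with late INP/iOSN and 0.436 for GBC with INP. For HBC with GBC the value was -0.111, and for GFP with the RING mutant under OMP -0.244. The main fits used no replicate numbers. Dates in the column names put the Mex3a libraries in 2016 and the RING mutant and GFP libraries in 2018, in different months, so date and transgene cannot be told apart in the comparisons between transgenes. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.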

Results

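RNA was measured in sorted cells of the mouse olfactory epithelium to follow Mex3a, an RNA-binding protein with a RING domain, along the olfactory sensory neuron lineage, after its forced expression and after its deletion. The lineage runs from horizontal basal cells (HBC) over globose basal cells (GBC) and immediate neuronal precursors (INP) to immature (iOSN) and mature olfactory sensory neurons (mOSN). Stage libraries of the SMARTer kit had 2 samples per group and between 25.7 and 39.5 M gene counts. The 3 control and 3 Mex3a conditional knockout (cKO) libraries had between 33.9 and 53.6 M. The 20 TruSeq libraries, 2 per group, had between 28.4 and 87.9 M. They covered wild-type stages and the tetO transgenes Mex3a, Mex3a with a mutated RING domain (RING mutant) and GFP, driven in mature neurons by OMP-tTA or in immature and mature neurons by gg8-tTA with OMP-tTA. RNA of the ribosome profiling samples was given as 1 value per group.

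Where along the lineage Mex3a is expressed was read from the SMARTer stages. Mex3a (ENSMUSG00000074480, chromosome 3, 88532395 to 88541396, GRCm38) stood at 34.2 ± 7.87 CPM in HBC, 379.9 ± 3.33 in GBC, 838 ± 32.8 in INP, 338 ± 93.1 in late INP/iOSN, 237 ± 19.96 in Atf5 iOSN and 8.80 ± 3.43 in mOSN (mean ± SD, n = 2 each). It rose from HBC to GBC by a log2 fold of 3.47 (SE 0.30, edgeR adjusted p = 6.0e-07) and from INP onward fell to the mature neurons, with a log2 fold of -4.75 (SE 0.32, edgeR adjusted p = 1.9e-07) at the last step alone. The rise from GBC to INP (log2 fold 1.14, SE 0.27, edgeR adjusted p = 0.00673) lost its call without either GBC library or without INP replicate 1 (log2 folds 1.02, 1.05 and 0.98). TruSeq libraries had 588 ± 73.4 CPM in GBC and 376 ± 52.1 in those labelled INP (n = 2 each, not tested). The latter held more OR transcripts than the SMARTer INP, as given below, so that this is not the same step. The fall from INP to late INP/iOSN (-1.31, SE 0.27, edgeR adjusted p = 0.00573) lost it without late INP/iOSN replicate 2 (-1.20). Between late INP/iOSN and Atf5 iOSN the log2 fold of -0.51 did not pass (edgeR adjusted p = 0.329).

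**Figure D1:**
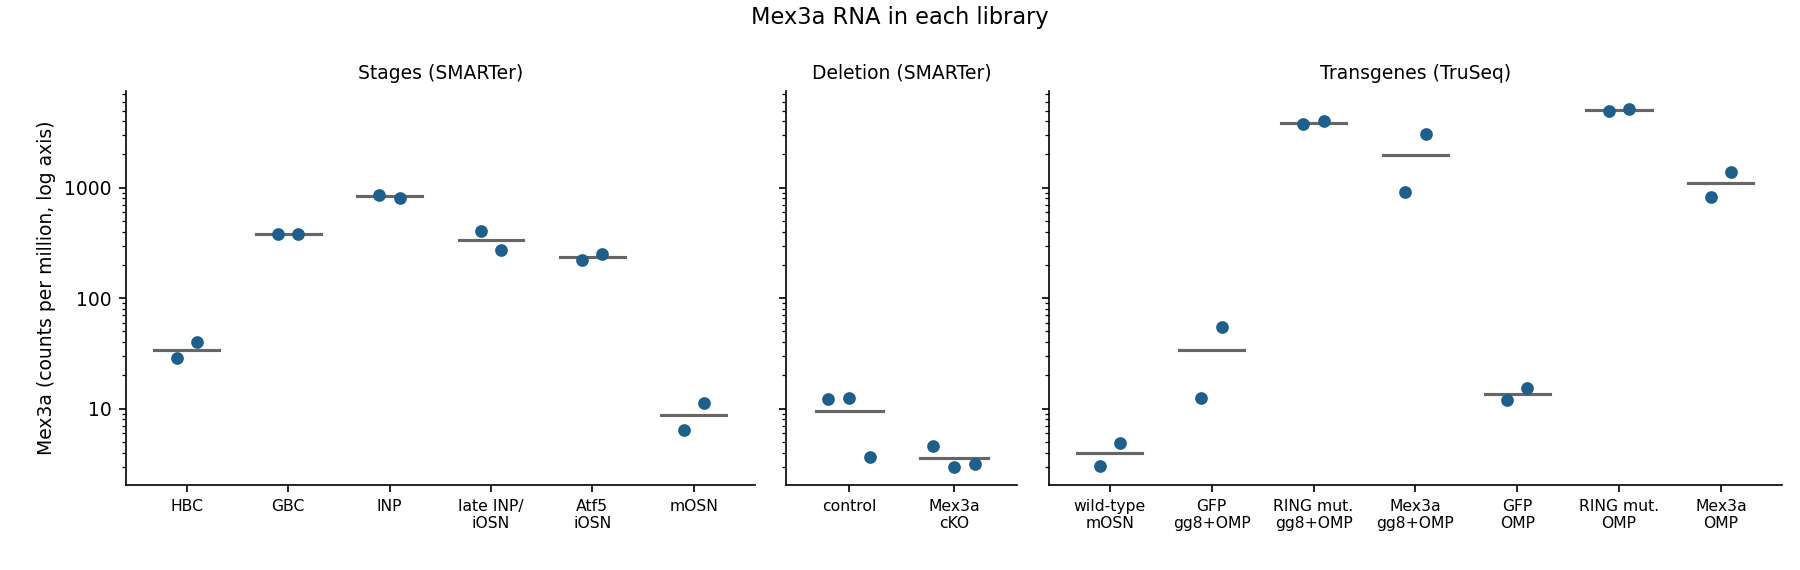
Mex3a in counts per M on a log axis for each library (points) with group means (grey bars), in the SMARTer stages, the SMARTer deletion libraries and the TruSeq libraries. Stage means ran from 34.2 in HBC over 838 in INP to 8.80 in mOSN, and the library labelled control replicate 3 stood at 3.65, beside 2.99 to 4.59 in the cKO libraries.

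GBC against HBC asked what sets dividing neuronal progenitors apart from reserve stem cells. The proneural factors Ascl1 (ENSMUSG00000020052, chromosome 10, 87490819 to 87493660) and Neurog1 (ENSMUSG00000048904, chromosome 13, 56250478 to 56252163) and the zinc finger factor Insm1 (ENSMUSG00000068154) were among the most strongly raised genes. Ascl1 rose from 0.801 ± 0.250 to 227 ± 16.1 CPM (log2 fold 8.13, SE 0.79, edgeR adjusted p = 2.1e-06) and Insm1 from 3.30 ± 0.694 to 348 ± 2.53. All 27 proliferation genes rose, among them Top2a (ENSMUSG00000020914), a topoisomerase of dividing cells, from 71.3 to 1276 CPM (camera adjusted p = 5.6e-32, adjusted p = 0.0562 with an estimated correlation). Of 10 GBC markers 9 rose, Kit (ENSMUSG00000005672) and Hes6 (ENSMUSG00000067071) among them (camera adjusted p = 4.1e-13, adjusted p = 0.0562 with an estimated correlation). All 13 HBC markers fell (camera adjusted p = 2.0e-22, adjusted p = 0.0621 with an estimated correlation). The keratin Krt14 (ENSMUSG00000045545) fell from 2142 ± 283 to 7.04 ± 3.41 CPM and Icam1 (ENSMUSG00000037405), the antigen used for the HBC sort, from 831 ± 44.6 to 4.27 ± 2.65. The Mex3 relatives Mex3b (ENSMUSG00000057706) and Mex3d (ENSMUSG00000048696) rose with Mex3a, with log2 folds of 2.27 and 1.36.

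HBC libraries also carried more transcripts of other cells. Of 15 immune markers 13 were lower in GBC, such as C1qa (ENSMUSG00000036887) at 0.504 against 65.0 CPM (camera adjusted p = 4.1e-13, adjusted p = 0.128 with an estimated correlation). The immunoglobulin light chain Igkc (ENSMUSG00000076609) was at 0 counts in GBC and at 48.1 ± 48.3 CPM in HBC, where the libraries lay far apart. Mature neuron markers fell in 19 of 25 cases, Omp (ENSMUSG00000074006) from 71.7 ± 14.5 to 2.94 ± 2.67 CPM (camera adjusted p = 2.2e-10, adjusted p = 0.171 with an estimated correlation). Beside these, 567 of 1076 olfactory receptor (OR) genes were lower in GBC and 0 higher (655 and 0 adjusted over the list alone, camera adjusted p = 7.5e-09, adjusted p = 0.624 with an estimated correlation), Olfr1226 (ENSMUSG00000075097) by at least 13.3-fold. Of 22 immediate early genes 21 were lower, Atf3 (ENSMUSG00000026628) at 99.8 ± 17.5 against 2311 ± 195 CPM (camera adjusted p = 1.7e-25, adjusted p = 0.0562 with an estimated correlation). In all, edgeR called 4680 genes higher and 6451 lower of 32100 tested, a balance that turned to 6390 higher and 4846 lower with replicate numbers as a block. Without GBC replicate 1 the total of 11131 dropped to 6944. The lower OR genes dropped to 242 without that library, to 224 without HBC replicate 1, to 339 with the block and to 153 with only the compared groups in the fit. Their median of -3.33, or -2.28 with genes at 0 in a group set to their bound, ran from -5.97 to -2.22 when single libraries were left out. The median of all genes lay at -0.66 and moved to -0.09 with only the compared groups in the fit.

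INP against GBC asked what neuronal commitment brings. The transcription factor gene Olig2 (ENSMUSG00000039830) went from 0.892 ± 0.269 to 274 ± 44.8 CPM (log2 fold 8.25, SE 0.34, edgeR adjusted p = 2.3e-09). Myt1l (ENSMUSG00000061911) rose from 6.50 ± 4.08 to 1559 ± 176 CPM and Neurog1 rose by a log2 fold of 5.20 to 1172 ± 475. Of 15 genes for OR choice and feedback 12 rose and 2 fell (13 and 2 adjusted over the list alone, camera adjusted p = 4.7e-25, adjusted p = 0.0481 with an estimated correlation). Lhx2 (ENSMUSG00000000247), a homeodomain factor bound at OR enhancers, rose from 18.7 ± 12.5 to 1584 ± 371 CPM and Ebf3 (ENSMUSG00000010476) from 9.94 to 1654. Immature neuron markers rose in 13 of 16 cases (camera adjusted p = 8.2e-36, adjusted p = 0.0481 with an estimated correlation). Gng8 (ENSMUSG00000063594) stood at 132 against 1.495 CPM and the growth cone protein Gap43 (ENSMUSG00000047261) at 67.6 against 1.74. Axon guidance genes went both ways, 16 of 41 higher and 11 lower (camera adjusted p = 0.00709, adjusted p = 0.206 with an estimated correlation). The semaphorin receptor Nrp2 (ENSMUSG00000025969) rose from 7.24 ± 0.805 to 717 ± 68.6 CPM. Among 40 adhesion genes 16 rose and 4 fell (17 and 4 adjusted over the list alone, camera adjusted p = 1.3e-07, adjusted p = 0.0481 with an estimated correlation), Ncam1 (ENSMUSG00000039542) from 27.7 to 1525 CPM. Ascl1 fell from 227 ± 16.1 to 9.63 ± 5.62 CPM and Kit from 650.1 ± 29.6 to 37.6 ± 8.16. OR transcripts appeared at low levels, 283 genes higher and 0 lower (321 and 1 adjusted over the list alone, camera adjusted p = 4.1e-08, adjusted p = 0.541 with an estimated correlation). Olfr876 (ENSMUSG00000066750), at 2.93 ± 0.477 CPM against 0, was at least 28.7-fold higher. The OR genes higher dropped to 114 without GBC replicate 1, to 174 without INP replicate 2 and to 93 with only the compared groups in the fit. The OR median of 2.57 dropped to 1.44 with the genes at 0 in a group set to their bound. It ran from 1.31 without INP replicate 2 to 4.76 without GBC replicate 2 when single libraries were left out. Genes higher numbered 3794 and lower 2739 by edgeR. The total of 6533 dropped to 4077 without GBC replicate 1 and to 4001 without GBC replicate 2.

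Late INP/iOSN against INP followed the exit from division. Proliferation genes fell in 24 of 27 cases (camera adjusted p = 2.0e-42, adjusted p = 0.0343 with an estimated correlation). Top2a fell from 470 ± 7.95 to 52.8 ± 39.8 CPM, and the precursor factor Neurod1 (ENSMUSG00000034701) dropped from 639 ± 186 to 56.0 ± 38.2. Mature neuron markers rose in 16 of 25 cases (camera adjusted p = 1.0e-30, adjusted p = 0.0354 with an estimated correlation). The olfactory channel gene Cnga2 (ENSMUSG00000005864) stood at 155 ± 40.2 against 12.1 CPM (log2 fold 3.68, SE 0.30, edgeR adjusted p = 9.5e-06) and Omp at 234 ± 69.6 against 36.9 ± 12.5. OR genes were higher in 428 cases and lower in 0 (684 and 0 adjusted over the list alone, camera adjusted p = 8.7e-46, adjusted p = 0.132 with an estimated correlation). Olfr681 (ENSMUSG00000095248) stood at 7.09 ± 4.09 CPM against 0. Adhesion genes rose in 18 of 40 cases and fell in 2 (18 and 3 adjusted over the list alone, camera adjusted p = 5.0e-09, adjusted p = 0.0354 with an estimated correlation). The teneurin Tenm2 (ENSMUSG00000049336) stood at 701 ± 100.8 against 69.4 ± 16.1 CPM and the contactin Cntn4 (ENSMUSG00000064293) at 811 against 84.2. The unfolded protein response gene Ddit3 (ENSMUSG00000025408) rose from 25.6 to 76.9 CPM and Trib3 (ENSMUSG00000032715), a pseudokinase induced in that response, from 6.36 to 73.9. Of the 24 members of that list 7 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 3.1e-06, adjusted p = 0.412 with an estimated correlation). edgeR called 1795 genes higher and 1416 lower, a balance that turned to 1427 higher and 1911 lower with replicate numbers as a block. The total of 3211 dropped to 2002 without INP replicate 1 and to 1505 without late INP/iOSN replicate 2, and the OR genes higher dropped to 253 and 250. The median of all genes was 0.20, and 0.02 with only the compared groups in the fit.

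Atf5 iOSN, sorted as cells positive for a reporter of Atf5 translation and negative for OMP-GFP, differed from late INP/iOSN in fewer genes, 266 higher and 719 lower by edgeR. With only the compared groups in the fit 1815 genes were called, near the 1822 of late INP/iOSN against INP, and with DESeq2 2253. The total of 985 dropped to 428 without Atf5 iOSN replicate 2, to 539 without Atf5 iOSN replicate 3 and to 594 without late INP/iOSN replicate 1. Neurog1 fell from 239 ± 10.8 to 2.76 ± 0.975 CPM (log2 fold -6.43, SE 0.50, edgeR adjusted p = 1.8e-05) and Neurod1 from 56.0 ± 38.2 to 3.82 ± 3.11. Of 12 INP markers 6 fell and 1 rose (camera adjusted p = 5.2e-14, adjusted p = 0.111 with an estimated correlation). The guidance receptors Ephb1 (ENSMUSG00000032537) and Dcc (ENSMUSG00000060534) fell, with log2 folds of -3.48 and -3.05. Of 15 immune markers 12 were higher in Atf5 iOSN (camera adjusted p = 2.0e-24, adjusted p = 0.111 with an estimated correlation), such as Ctss (ENSMUSG00000038642) at 17.4 ± 12.5 against 0.541 ± 0.297 CPM. Of 22 immediate early genes 10 were higher (13 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.3e-16, adjusted p = 0.111 with an estimated correlation). OR genes were higher in 12 cases and lower in 0, with 0 in either direction adjusted over the list alone (camera adjusted p = 4.9e-09, adjusted p = 0.695 with an estimated correlation). The 12 became 4 without Atf5 iOSN replicate 2, 2 higher and 2 lower without late INP/iOSN replicate 1, and 8 higher and 10 lower without Atf5 iOSN replicate 3.

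mOSN against Atf5 iOSN covered maturation. The calcium-binding protein gene S100a5 (ENSMUSG00000001023) rose from 6.70 ± 1.05 to 1832 ± 687 CPM (log2 fold 8.09, SE 0.51, edgeR adjusted p = 1.2e-07). Of 25 mature neuron markers 22 rose and 1 fell (camera adjusted p = 7.6e-45, adjusted p = 0.0315 with an estimated correlation). Omp stood at 1926 ± 335 against 185 ± 10.7 CPM. Immature neuron markers fell in 14 of 16 cases (camera adjusted p = 7.8e-31, adjusted p = 0.0579 with an estimated correlation), Gap43 from 899 ± 45.5 to 47.5 ± 14.03 CPM. Mex3b and Mex3d fell beside Mex3a, with log2 folds of -3.25 and -2.59 (3 of 4 family members called, 4 of 4 adjusted over the list alone, camera adjusted p = 5.0e-12, adjusted p = 0.0315 with an estimated correlation). Guidance and adhesion genes went both ways. The adhesion proteins Kirrel2 (ENSMUSG00000036915) and Kirrel3 (ENSMUSG00000032036), which take part in the sorting of olfactory axons, rose by log2 folds of 2.77 and 2.15 and the ephrin receptor Epha5 (ENSMUSG00000029245) by 4.44. Ephb2 (ENSMUSG00000028664) fell from 72.5 ± 1.27 to 5.18 ± 0.262 CPM. OR genes were higher in 109 cases and lower in 38 (95 and 34 adjusted over the list alone, camera adjusted p = 0.0212, adjusted p = 0.788 with an estimated correlation). The split became 25 and 24 without Atf5 iOSN replicate 2, 31 and 22 without mOSN replicate 2 and 55 and 20 without mOSN replicate 1, but 389 and 87 with only the compared groups in the fit. edgeR called 2608 genes higher and 2834 lower. With DESeq2 the split was 4106 and 2974, and the median of all genes was 0.27, or 0.04 with only the compared groups in the fit. The total of 5442 dropped to 2851 without Atf5 iOSN replicate 2 and to 3040 without Atf5 iOSN replicate 3.

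TruSeq libraries of wild-type mOSN were set against those labelled INP in that kit. These were unlike the SMARTer INP, with an OR share of 0.398 ± 0.0306% against 0.0376 ± 0.00986%, so that they did not repeat the same step. Mex3a fell from 376 ± 52.1 to 3.98 ± 1.36 CPM (log2 fold -6.56, SE 0.68, edgeR adjusted p = 3.6e-06), Neurog1 from 399 ± 25.6 to 0.110 ± 0.0929. All 12 INP markers fell (camera adjusted p = 6.7e-17, adjusted p = 0.0686 with an estimated correlation). Of 1080 OR genes 609 were higher in mOSN and 33 lower (662 and 41 adjusted over the list alone, camera adjusted p = 3.8e-19, adjusted p = 0.178 with an estimated correlation). Olfr1048 (ENSMUSG00000075195), at 6.70 ± 0.779 CPM against 0, was at least 123-fold higher. The OR genes higher dropped to 360 without the female INP library, and those lower to 21 without it, to 18 without the male INP library and to 6 without the female mOSN library. Omp, at 1693 ± 208 and 1555 ± 223 CPM, did not pass (edgeR adjusted p = 0.80), although 22 of 25 mature markers rose, such as the channel gene Cnga4 (ENSMUSG00000030897) from 82.3 ± 13.3 to 1464 ± 48.2 CPM. Across 27339 genes, which are not independent replicates, the log2 folds of mOSN over INP in both kits had a Pearson correlation of 0.539 and a Spearman correlation of 0.565.

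Whether Mex3a lowers OR transcripts was tested by forced expression. With both drivers Mex3a stood at 918 and 3040 CPM in the transgenic libraries and at 12.6 and 55.4 in GFP (log2 fold 5.87, SE 0.65, edgeR adjusted p = 1.2e-05). OR transcripts were lost almost across the family: 925 of 1080 genes fell and 1 rose, Olfr427 (ENSMUSG00000059371), with 954 and 1 adjusted over the list alone. Olfr586 (ENSMUSG00000066268, chromosome 7, 103118403 to 103125638) had 0 counts with Mex3a and 8.996 ± 0.153 CPM with GFP, at least 179.6-fold lower (edgeR adjusted p = 6.2e-07), and Olfr743 (ENSMUSG00000094285) and Olfr1251 (ENSMUSG00000111567) were at least 159-fold and 148-fold lower. The OR median was -4.33, or -4.02 with genes at 0 in a group set to their bound (camera adjusted p = 1.2e-69, adjusted p = 0.0657 with an estimated correlation). Trace amine receptors fell in 11 of 13 cases (camera adjusted p = 1.2e-06, adjusted p = 0.198 with an estimated correlation), Taar2 (ENSMUSG00000059763) from 10.2 ± 3.87 to 0.224 ± 0.0507 CPM.

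Neuronal maturation genes moved in the same libraries. Mature markers fell in 23 of 25 cases and 0 rose, with a median of -2.22 (camera adjusted p = 1.0e-21, adjusted p = 0.101 with an estimated correlation). Cnga4 fell from 471 ± 27.1 to 32.5 ± 1.49 CPM (log2 fold -3.86, SE 0.28, edgeR adjusted p = 6.4e-07), the adenylyl cyclase of odour transduction Adcy3 (ENSMUSG00000020654) from 713 ± 2.75 to 85.8 ± 17.3, and Omp from 2559 ± 12.6 to 613 ± 22.3. Of 12 INP markers 9 rose, Neurod1 from 14.95 ± 13.9 to 128 ± 37.9 CPM (camera adjusted p = 3.8e-06, adjusted p = 0.220 with an estimated correlation). Of 16 immature markers 9 rose, the tubulin Tubb3 (ENSMUSG00000062380) from 399.8 ± 59.96 to 1792 ± 398.5 CPM (camera adjusted p = 3.8e-06, adjusted p = 0.198 with an estimated correlation). OR choice genes split into 6 higher, with Lhx2 at a log2 fold of 1.41, and 5 lower, with the OR trafficking genes Rtp1 (ENSMUSG00000033383) and Rtp2 (ENSMUSG00000047531) at -1.77 and -2.22 (camera adjusted p = 0.883). Axon guidance genes rose in 14 of 41 cases and fell in 7 (15 and 7 adjusted over the list alone, camera adjusted p = 0.0254, adjusted p = 0.312 with an estimated correlation). Ephb2 rose from 15.9 ± 6.92 to 120.5 ± 37.2 CPM and Epha5 fell from 98.4 ± 25.9 to 15.01 ± 1.70. Kirrel2 fell from 745 ± 74.6 to 78.5 ± 5.57 CPM. Sustentacular markers had a median of 0.40 with 1 of 14 members called, and endothelial markers fell in 9 of 11 cases (camera adjusted p = 4.2e-04, adjusted p = 0.198 with an estimated correlation). edgeR called 4367 genes higher and 5198 lower of 28859. The total of 9565 dropped to 6177 without GFP replicate 1 and to 6313 without Mex3a library F2.

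With the OMP driver alone, which acts in mature neurons, Mex3a stood at 832.7 and 1387 CPM against 12.02 and 15.4 in GFP (log2 fold 6.34, SE 0.67, edgeR adjusted p = 2.7e-05). OR genes again fell, 797 of 1080 with 0 higher (904 and 0 adjusted over the list alone), with a median of -3.03 and a camera call kept with an estimated correlation (camera adjusted p = 1.8e-69, adjusted p = 0.0230 with an estimated correlation). The OR median ran from -4.12 without Mex3a library F1 to -2.49 without F2. Olfr1000 (ENSMUSG00000075215), at 0 counts with Mex3a and 2.45 ± 0.770 CPM with GFP, was at least 27.3-fold lower. Mature markers fell in 19 of 25 cases with a median of -1.39 (camera adjusted p = 5.7e-13, adjusted p = 0.211 with an estimated correlation). Cnga4 fell from 639 ± 95.1 to 78.2 ± 1.28 CPM and Omp from 3379 ± 277 to 1708 ± 174. The growth cone genes Gap43 and Dpysl5 (ENSMUSG00000029168) rose, Dpysl5 from 47.8 ± 11.96 to 261 ± 26.8 CPM. Of 16 immature markers 4 rose (camera adjusted p = 0.00564, adjusted p = 0.656 with an estimated correlation). Sema6c (ENSMUSG00000038777), a semaphorin, rose from 17.7 ± 1.90 to 60.1 ± 1.22 CPM and Nrp2 from 198 ± 28.8 to 386 ± 10.9. Of 41 guidance genes 9 rose and 3 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.252). Adhesion genes rose in 12 of 39 cases and fell in 3 (12 and 6 adjusted over the list alone, camera adjusted p = 0.0233, adjusted p = 0.656 with an estimated correlation). Lhx2, at 149 and 137 CPM, did not pass (edgeR adjusted p = 0.709). Of the other cell types, 9 of 11 endothelial and 9 of 13 HBC markers were lower with Mex3a, with medians of -2.34 and -1.82 (camera adjusted p = 8.6e-08 and 4.0e-06, adjusted p = 0.0613 and 0.275 with an estimated correlation). edgeR called 2325 genes higher and 4021 lower, a total that dropped from 6346 to 2678 without GFP replicate 1, to 3500 without GFP replicate 2 and to 4109 without Mex3a library F1. Without GFP replicate 1 only 439 genes were higher. Against wild-type mOSN the balance turned to 4911 higher and 4402 lower, and 3789 of the 4125 genes called in both kept their direction. The OR genes lower dropped to 528 without Mex3a library F2. Inhbb (ENSMUSG00000037035, chromosome 1, 119415465 to 119422248), an activin subunit gene, fell from 117 ± 24.9 to 0.151 ± 0.0548 CPM against GFP but had a log2 fold of 0.58 against wild-type mOSN.

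The Mex3a effect differed between the drivers, by an interaction test, in 1159 genes with a higher and 1212 with a lower fold when gg8 was added. Of the OR genes 2 had a higher and 68 a lower fold (1 and 57 adjusted over the list alone), with a median difference of -1.29 (camera adjusted p = 6.2e-09, adjusted p = 0.571 with an estimated correlation). F1 and F2 name founders with different insertion sites, which recur under both drivers. With the founder as a term, chosen after the data had been seen, the median was -1.24 with 110 OR genes lower and 3564 genes called. Within founder F1 alone it was -1.71, with 118 lower, and within F2 alone -0.50, with 14 lower and 1278 genes called. Without Mex3a OMP library F1, which leaves F1 unpaired, the median was -0.19 and 7 OR genes had a lower fold. Leaving out each other library gave between 12 and 211 such genes, with medians from -1.82 to -1.18. The basal keratin Krt5 (ENSMUSG00000061527) had a higher fold with both drivers, by 4.24 (SE 0.64, edgeR adjusted p = 0.0048). Immediate early genes had a higher fold with both drivers in 9 of 22 cases, Egr1 (ENSMUSG00000038418) by 1.94 (camera adjusted p = 1.2e-10, adjusted p = 0.311 with an estimated correlation). Mex3a itself did not pass (-0.48, edgeR adjusted p = 0.73). With only the compared groups in the fit 247 genes were called, with 14 OR genes lower, and with DESeq2 4797, with 192 lower. The 2371 genes dropped to 349 without Mex3a gg8 library F2, 399 without GFP gg8 replicate 1, 318 and 494 without either GFP OMP library and 412 without Mex3a OMP library F1, and rose to 4382 without Mex3a OMP library F2.

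The RING mutant tested whether the RING domain is needed. Its libraries held more Mex3a transcript than those of intact Mex3a, 3752 and 3986 CPM with both drivers and 4958 and 5151 with OMP alone. With both drivers the log2 fold of intact Mex3a over the mutant was -0.97. It ran from -2.07 without Mex3a library F2 to -0.31 without F1, since F2 at 3040 CPM lay close to the mutant. OR genes fell less widely: with both drivers 348 were lower and 9 higher than in GFP (399 and 11 adjusted over the list alone), with a median of -1.33 (camera adjusted p = 1.1e-10, adjusted p = 0.297 with an estimated correlation). With OMP alone 290 were lower and 7 higher (305 and 7 adjusted over the list alone), with a median of -1.003 (camera adjusted p = 8.6e-05, adjusted p = 0.724 with an estimated correlation). Olfr722 (ENSMUSG00000048933) fell with both, from 13.9 ± 5.06 to 0.434 ± 0.198 CPM and from 11.4 ± 0.339 to 0.261 ± 0.0366. Mature markers fell in 9 of 25 cases with both drivers (camera adjusted p = 0.00135, adjusted p = 0.529 with an estimated correlation). With OMP alone 1 rose and 1, Cnga4, fell from 639 ± 95.1 to 253 ± 11.8 CPM (camera adjusted p = 0.611). Mex3b rose with both drivers from 18.7 ± 11.5 to 132 ± 59.0 CPM, and Pcdh8 (ENSMUSG00000036422), a protocadherin, rose with OMP from 49.5 ± 17.8 to 350 ± 82.5. These libraries held far fewer transcripts of other cells: sustentacular markers were lower in 13 of 14 and 14 of 14 cases, with medians of -3.94 and -4.23 (camera adjusted p = 6.1e-16 and 6.6e-15, adjusted p = 0.108 and 0.145 with an estimated correlation), and Cyp2g1 (ENSMUSG00000049685), an abundant sustentacular enzyme, stood at 105 against 2513 and at 126 against 2946 CPM. In mean log2 CPM of the sustentacular markers the RING mutant libraries lay at 2.90 to 4.02, near wild-type mOSN at 3.78 and 3.86. GFP libraries lay at 7.10 to 7.87 and Mex3a libraries at 6.46 to 7.65. edgeR called 2370 genes higher and 4211 lower with both drivers and 2244 and 4785 with OMP. With the sustentacular level as a covariate, chosen after the data had been seen, 74 and 816 genes passed, with 2 and 10 OR genes lower and OR medians of -1.41 and -1.09. As the RING mutant and GFP libraries do not overlap in that level, the covariate cannot part it from the transgene. Without GFP replicate 1 the genes higher with both drivers dropped from 2370 to 557. With both drivers the OR genes lower dropped to 111 without RING mutant replicate 2 and to 225 without GFP replicate 2. With OMP alone they dropped to 125 and 135 without either RING mutant library and to 137 without GFP replicate 1. They rose to 529, with 67 higher, with replicate numbers as a block, to 495 and 48 with only the compared groups in the fit, and to 528 and 8 against wild-type mOSN. Against wild-type mOSN the OR median was -1.97. RING mutant replicate 2 with both drivers is the only library whose column name carries a read length. Its OR share was 0.169%, against 0.2525% in the unnumbered library, and an effect of read length was not tested.

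Set against the RING mutant directly, intact Mex3a left 737 OR genes lower and 1 higher with both drivers (842 and 1 adjusted over the list alone), with a median of -2.92 (camera adjusted p = 4.4e-44, adjusted p = 0.133 with an estimated correlation). With OMP alone 501 were lower and 0 higher (625 and 1 adjusted over the list alone), with a median of -2.03 (camera adjusted p = 1.1e-45, adjusted p = 0.108 with an estimated correlation). Olfr1102 (ENSMUSG00000049843) had 0 counts with intact Mex3a and 2.17 ± 1.40 CPM with the mutant with both drivers. Mature markers fell in 21 and 20 of 25 cases (camera adjusted p = 2.4e-14 and 3.2e-17, adjusted p = 0.144 and 0.108 with an estimated correlation), Cnga4 with log2 folds of -1.87 and -1.69. Pcdh8 fell from 350 ± 82.5 to 25.9 ± 2.53 CPM with OMP alone. Immediate early genes were higher in 19 of 22 cases with both drivers (20 adjusted over the list alone, camera adjusted p = 2.2e-20, adjusted p = 0.0725 with an estimated correlation), Egr1 at 212 ± 32.2 against 24.9 ± 1.40 CPM. Sustentacular markers were higher in 13 of 14 and 14 of 14 cases beside them (camera adjusted p = 7.3e-15 and 8.9e-16, adjusted p = 0.133 and 0.108 with an estimated correlation). edgeR called 4547 genes higher and 4091 lower with both drivers and 3185 and 2695 with OMP. With the sustentacular level as a covariate 685 and 1992 genes passed, with 49 and 42 OR genes lower and OR medians of -2.86 and -1.98. That level lay at 6.46 to 7.65 in the Mex3a and at 2.90 to 4.02 in the RING mutant libraries (mean log2 CPM). With no overlap between them, the covariate cannot part it from the transgene and decides nothing here. With OMP alone the OR median ran from -3.21 without Mex3a library F1 to -1.56 without F2. With both drivers the total of 8638 dropped to 5247 without the unnumbered RING mutant library, with 481 OR genes lower, and to 5319 without Mex3a library F2. With OMP alone the total of 5880 dropped to 2259 without RING mutant replicate 2, with 247 OR genes lower, and to 3315 without replicate 1. Without Mex3a library F2, 213 OR genes were lower with OMP. Mex3a itself was lower than the mutant with OMP alone (-2.19, edgeR adjusted p = 0.0116), a call lost without Mex3a library F1 (-1.95, edgeR adjusted p = 0.0735) and with the covariate (-1.38, edgeR adjusted p = 0.488).

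Both transgenes were compared with the same GFP libraries, which alone makes their folds correlate. Across genes, which are not independent replicates, the correlation of the Mex3a and RING mutant folds was 0.461 with both drivers, where sharing the control gave 0.491 in simulations, and 0.561 against 0.501 with OMP. The covariance was 1.05 against a simulated 0.237 and 1.18 against 0.249. With both drivers 1779 genes were lower with both transgenes, 345 of them OR genes, and with OMP alone 2000 and 282. Sharing the control raises these counts by itself, to an extent that was not simulated.

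The OR share of all gene counts summed these changes. It was 0.549 ± 0.0330% with GFP and 0.0327 ± 0.0103% with Mex3a under both drivers, 16.8-fold lower, and 0.620 ± 0.0507% and 0.0839 ± 0.0538% under OMP, 7.38-fold lower (n = 2 each). The ratio under OMP of 0.135 became 0.074 without Mex3a library F1 and 0.197 without F2. The RING mutant stood at 0.211 ± 0.0588% and 0.334 ± 0.0475%, 2.60-fold and 1.86-fold lower than GFP. No library of a transgene group overlapped with its GFP group, and each exact two-sided permutation test gave p = 0.333, the smallest that 2 against 2 libraries allow. Among the SMARTer stages the share went from 0.0376 ± 0.00986% in INP to 0.260 ± 0.0608% in late INP/iOSN and 0.669 ± 0.0783% in mOSN. The effective number of OR genes was 321 ± 49.1 with Mex3a and 443.5 ± 9.80 with GFP under both drivers (exact two-sided p = 0.333) and 522.5 ± 5.80 and 532 ± 14.03 under OMP (exact two-sided p = 0.667).

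**Figure D2:**
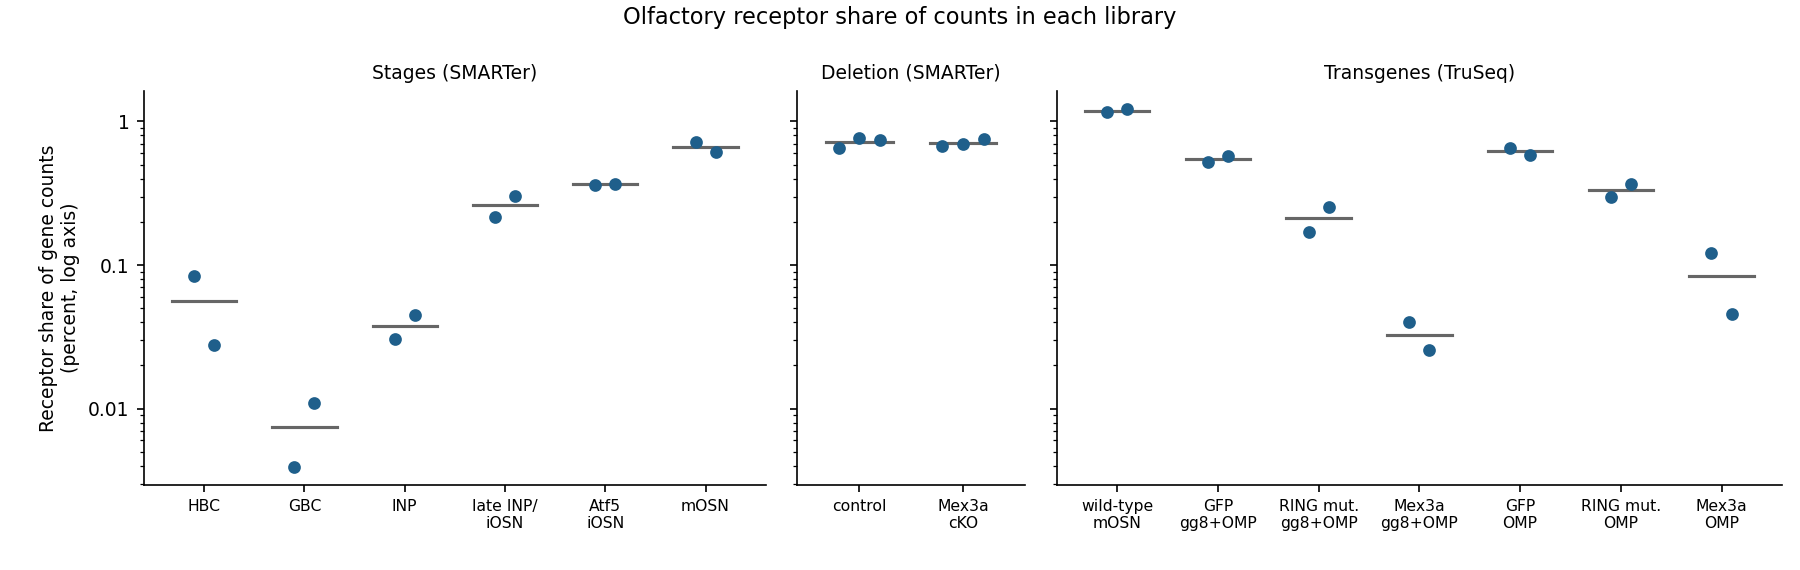
Share of gene counts on olfactory receptor genes in percent on a log axis for each library (points) with group means (grey bars), in the SMARTer stages, the SMARTer deletion libraries and the TruSeq libraries. The Mex3a groups average 0.0327 and 0.0839%, below their GFP groups at 0.549 and 0.620%, while cKO and control stand at 0.709 and 0.725%.

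OR genes fell further than the mature markers. The OR median lay below the median of mature markers by a log2 difference of -2.11 (95% bootstrap interval over genes -2.46 to -1.66) with Mex3a under both drivers and -1.64 (-2.03 to -1.37) under OMP. For the RING mutant the differences were -0.83 (-1.02 to -0.42) and -1.05 (-1.47 to -0.50).

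**Figure D3:**
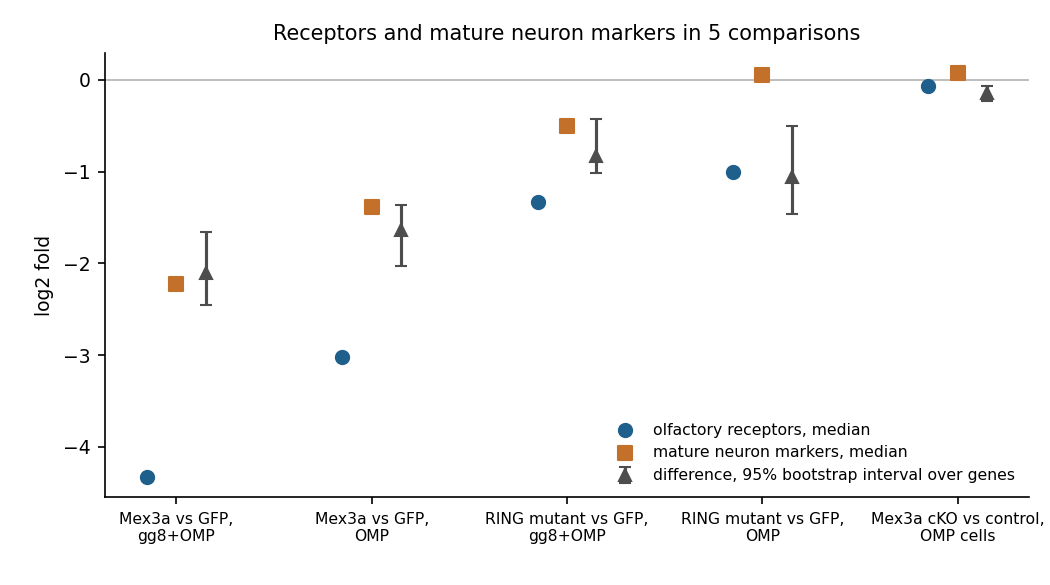
Median log2 folds of olfactory receptors (circles) and mature neuron markers (squares) and their difference with its 95% bootstrap interval over genes (triangles) for 5 comparisons. The difference is -2.11 and -1.64 for Mex3a, -0.83 and -1.05 for the RING mutant and -0.14 for the deletion.

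Exonic and intronic counts under the OMP driver were set against each other as a proxy for spliced and unspliced RNA. Introns can also hold reads of overlapping genes: Cenpo (ENSMUSG00000020652) had 1668 CPM in introns and 12.96 in exons with GFP. OR exons had a median log2 fold of -2.42 and OR introns of -1.52, over 469 genes with enough of both. These folds add a small constant to each mean CPM, which shrinks those of genes with few counts. All OR introns held 9328 and 2914 counts in Mex3a libraries F1 and F2, and 36790 and 48264 with GFP. The gap between both medians can thus come from this constant. The fitted exonic minus intronic change of OR genes had a median of -0.30, which is -0.79 relative to all genes, with 7 genes higher and 28 lower (3 and 7 adjusted over the list alone, camera adjusted p = 5.9e-12, adjusted p = 0.491 with an estimated correlation). Mature markers had a median of -0.17, which is -0.66 relative to all genes and thus near that of the OR genes. Of 24 such markers 4 were higher and 7 lower (camera adjusted p = 8.5e-04, adjusted p = 0.740 with an estimated correlation). Among the named genes Mex3a had the largest exonic excess at 5.15 (SE 0.30, edgeR adjusted p = 3.3e-06), its exons at 6.52 and its introns at 1.38. As Mex3a is itself the transgene, this excess cannot be told apart from transgene RNA. The kinase gene Camk2b (ENSMUSG00000057897) stood at 3.53, with exons at 4.12 and introns at 0.72. Ribosomal protein genes rose in 49 of 71 cases (camera adjusted p = 2.0e-07, adjusted p = 0.740 with an estimated correlation), and sustentacular markers in 13 of 13. The median of all genes was 0.49, or 0.12 with TMM factors, and the edgeR calls went from 3583 higher and 641 lower to 1676 and 1610 with these. Without a term per library the calls numbered 235, with 178 higher and 57 lower. Introns took 25.3 and 26.3% of counts with GFP and 35.7 and 47.5% with Mex3a. The total of 4224 dropped to 929 and 1067 without either GFP library and rose to 7356 without Mex3a library F2.

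The deletion asked what OMP-positive neurons that lacked Mex3a look like. Mex3a stood at 12.3, 12.6 and 3.65 CPM in the control and at 4.59, 2.99 and 3.18 in the cKO libraries, so that the library labelled control replicate 3 lay at the level of the cKO. The log2 fold of -1.41 did not pass (SE 0.39, edgeR adjusted p = 0.269), and without that library it was -1.80 (edgeR adjusted p = 0.0149). With it included, 29 genes were higher and 62 lower of 23407 by edgeR, and 1728 had an unadjusted p under 0.05. The glutamate receptor subunit Grin2b (ENSMUSG00000030209, chromosome 6, 135713233 to 136173511) fell from 38.9 ± 5.30 to 7.81 ± 3.74 CPM (n = 3, log2 fold -2.31, SE 0.28, edgeR adjusted p = 0.00751), the neurofilament Nefl (ENSMUSG00000022055) from 11.4 ± 2.42 to 2.44 ± 0.813, and Bend4 (ENSMUSG00000092060) from 30.3 ± 7.86 to 11.04 ± 1.21. Tenm1 (ENSMUSG00000016150), a teneurin, fell from 29.1 ± 2.12 to 17.4 ± 0.392 CPM. Rhbdl3 (ENSMUSG00000017692) rose from 15.8 ± 2.59 to 32.3 ± 1.13 CPM and the relative Mex3c (ENSMUSG00000037253) from 162 ± 21.2 to 227 ± 3.77 (edgeR adjusted p = 0.0497).

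Single OR genes changed in the cKO. Of 1023, 16 were higher and 20 lower (43 and 84 adjusted over the list alone), with a median of -0.07 (camera adjusted p = 0.163). These became 4 and 11, 5 and 8 and 8 and 19 without cKO replicates 1, 2 and 3, and 11 and 13, 7 and 12 and 13 and 12 without control replicates 1, 2 and 3. With DESeq2 they were 43 and 76, and without a low-count filter 72 and 131. Olfr1507 (ENSMUSG00000059887) fell from 55.3 ± 15.9 to 11.7 ± 0.791 CPM (log2 fold -2.25, SE 0.19, edgeR adjusted p = 0.00126), Olfr727 (ENSMUSG00000059488) from 17.6 ± 3.66 to 4.24 ± 0.292. The neighbours Olfr1180 (ENSMUSG00000081836, chromosome 2, 88410649 to 88419151) and Olfr1181 (ENSMUSG00000075125, chromosome 2, 88420321 to 88426171) fell from 1.96 ± 0.873 to 0.00644 ± 0.0112 CPM and from 3.49 ± 2.62 to 0.269 ± 0.0285. Olfr750 (ENSMUSG00000035932) rose from 3.44 ± 0.946 to 10.8 ± 2.49 CPM. Class I receptors had a median of -0.31 with 0 called over all genes (0 higher and 7 lower adjusted over the list alone, camera adjusted p = 1.9e-05, adjusted p = 0.336 with an estimated correlation). Adhesion genes had 1 of 37 lower (3 adjusted over the list alone, camera adjusted p = 4.5e-05, adjusted p = 0.317 with an estimated correlation), and 0 of 40 axon guidance genes were called, Nrp2 at 239 against 284 CPM. Ventral epithelium genes were lower as well (median -0.23, 0 of 6 called, 2 adjusted over the list alone, camera adjusted p = 5.9e-07, adjusted p = 0.317 with an estimated correlation). Markers of other cells were higher with 0 called over all genes, endothelial markers by a median of 0.48 and immune markers of 0.50 (camera adjusted p = 1.9e-05 and 0.00823, adjusted p = 0.317 and 0.393 with an estimated correlation). So were histones, proliferation genes and mature markers, by 0.26, 0.14 and 0.08 (camera adjusted p = 2.2e-07, 0.00791 and 0.00791, adjusted p = 0.401, 0.594 and 0.853 with an estimated correlation). Immature markers passed camera only with replicate numbers as a block (adjusted p = 0.0122, against 0.0648 without it). The OR share was 0.709 ± 0.0391% against 0.725 ± 0.0596% (exact two-sided p = 0.8), and the effective number of OR genes was 600.4 ± 22.1 against 639.5 ± 8.11 (exact two-sided p = 0.1, the smallest that 3 against 3 libraries allow). The 91 genes dropped to 42, 27 and 56 without cKO replicates 1, 2 and 3, to 47 without control replicate 2 and to 55 without the library labelled control replicate 3. Olfr692 (ENSMUSG00000073906) and Olfr1076 (ENSMUSG00000060742), both higher, lost their call when single libraries were left out.

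RNA of the ribosome profiling samples, with 1 value per group and no replicate check, gave Mex3a at 108 CPM in control Ngn cells (95% Wilson interval 105.8 to 110.1) and 23.6 in cKO (21.9 to 25.5), and at 12.2 (11 to 13.4) and 1.41 (1.03 to 1.94) in OMP cells. OR RNA had a median log2 ratio of 0.22 in Ngn cells over 393 genes, at percentile 99.4 of matched random lists, and 0.21 in OMP cells over 421 genes, at percentile 100. In OMP cells mature neuron markers shifted as well, by 0.16 (percentile 100), while in Ngn cells their median of 0.23 lay within the range of random lists. In Ngn cells clustered protocadherins (0.36), ribosomal protein genes (-0.83) and histones (-1.68) lay outside theirs, so a shift was not particular to receptors. The median ratio of all genes was 0.10 in Ngn and -0.02 in OMP cells. In Ngn cells the limit of 100 reads, at 27.8 M reads in cKO and 89.3 M in control, can favour receptors that are higher in cKO. Over all receptors, with no such limit, the OR share was lower in Ngn cKO, at 0.3999% against 0.433% in control. In OMP cells it was 0.496% in cKO and 0.460% in control. The log2 ratio of OR translation efficiency, cKO over control, had a median of -0.05 in Ngn cells. This lay above the range of random lists, from -0.40 to -0.17. In OMP cells it was -0.12, at percentile 59.4. In Ngn cells histones (1.485), ribosomal protein genes (0.24) and proliferation genes (0.20) were among the other lists above their ranges. INP (-0.69) and sustentacular markers (-0.66) were among those below. Clustered protocadherins, cell surface proteins of neuronal identity, had a median log2 ratio of translation efficiency of 0.31 in OMP cells, at percentile 99.99. There mRNA decay genes (0.19) also lay above their range. Mitochondrial transcripts (-0.78), ribosomal protein genes (-0.57) and histones (-0.36) lay below theirs. Sustentacular markers differed in both cells, with median RNA ratios of -1.72 in Ngn and 1.60 in OMP cells and Cyp2g1 at 34.2 against 333 and at 105 against 19.6 CPM.

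Called cKO genes moved alike in the profiling RNA. Of 59 measured in OMP cells 55 had the same direction, and of the 19 OR genes among them 17. Over all 10562 genes measured in both, 57.7% had the same sign, with a Pearson correlation of 0.311. In Ngn cells the counts were 47 of 56 and 18 of 20. Across 420 OR genes, which are not independent replicates, the SMARTer and OMP profiling folds correlated at 0.534 (Pearson) and 0.468 (Spearman), and 67.1% had the same sign. Folds of the deletion and of Mex3a under OMP correlated at -0.03 over 22663 genes and at 0.264 over 1021 OR genes.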

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

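The tests of explanations in this part were chosen after the results were seen. A test of the difference between both driver settings set apart 2371 genes whose Mex3a effect differed, and the olfactory receptor genes had a median log2 difference of -1.29 there. Within founder F1 of the transgene it was -1.71 and within founder F2 -0.50, with 1 Mex3a library per driver each. The same interaction test for the RING mutant set apart 69 genes, 68 with a higher and 1 with a lower fold under both drivers, and 1 of these was a receptor gene. The GBC and HBC libraries of the TruSeq kit, which no comparison used, carried a Mex3a difference with a log2 fold of 4.28 (SE 0.60, edgeR adjusted p = 2.2e-05), at 588 ± 73.4 against 30.3 ± 1.93 CPM (n = 2 each).

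The fall of olfactory receptors with the Mex3a transgene may come from fewer mature neurons in the sorted cells, from more precursors, or from libraries made in 2016 being set against GFP libraries of a later year. Dilution by cells that hold neither would lower receptors and mature markers alike. The receptor median, however, lay below the marker median by a log2 difference of -1.64 under OMP. The bootstrap interval, which is over genes and not over libraries, was under 0 with both drivers. Cells that hold the markers were weighed for both drivers only, so under OMP alone their admixture was not tested. For more precursors under both drivers the stages divide. TruSeq INP libraries hold too many receptor counts, since the highest share with Mex3a was 0.106 of their lowest share, and SMARTer late INP/iOSN and Atf5 iOSN do as well. SMARTer INP, at 0.0376 ± 0.00986%, and TruSeq GBC, at 0.0418 ± 0.00551%, had shares as low as with Mex3a. A mixture of mature neurons with these or with the remaining HBC and GBC libraries could not hold the mature markers, whose median lay above the most such a mixture allows by at least 0.85 on the log2 scale. The nearest was TruSeq GBC against Mex3a library F1, with an interval from 0.0388 to 1.16. SMARTer stages enter that bound as ratios to the mature neurons of their own kit, and mixtures of more stages were not tested. With Mex3a under OMP the receptor median against wild-type mature neurons of 2016 was -4.08, which argues against the year as the whole cause there. These wild-type libraries differ in more than the year. Their sustentacular level was 3.78 and 3.86, against 6.46 and 7.32 with Mex3a under OMP (mean log2 CPM). For both drivers this comparison was not made. A change in the state of the neurons, in which mature markers fell as well, stays open and was not tested apart from an effect on the receptors themselves.

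The lower olfactory receptors with the RING mutant came with sustentacular markers lower by medians of -3.94 and -4.23. Less RNA of non-neuronal cells would leave receptors and mature markers at or above their GFP level. The receptor median, however, lay below the marker median by a log2 difference of -1.05 under OMP. The bootstrap interval, again over genes and not over libraries, was under 0 with both drivers. With the sustentacular level as a covariate the receptor medians were -1.41 and -1.09, with 2 and 10 receptor genes still called lower. That level lay at 2.90 to 4.02 in the RING mutant and at 7.10 to 7.87 in the GFP libraries (mean log2 CPM). The groups do not overlap in it, so the covariate cannot part it from the transgene and decides nothing here. A weaker residual activity of the mutant may account for the lower receptors, which was not tested.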

How the results depend on the processing

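The covariate, the wild-type control, the crossed numbers and the founder settings were chosen after seeing the data. Of 229 alternatives for counts and receptor measures, 167 stayed within 1.5 times the count or within 1 SD of the measure and 62 did not. The 167 include every receptor share and effective number with a library left out. Their SD comes from the same libraries, so those settings say nothing of stability and the 167 overstate it. Of 2285 log2 folds of named genes under alternatives, 2065 kept their direction and side of the threshold, 212 lost the call, 4 gained a call and 4 reversed. The cause was not tested in any of these cases. Tests planned for the ribosome profiling RNA were not run because it has 1 value per group. In groups of 2, leaving out a library assumes that the lone sample varies like the other groups.

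With only the compared groups in the fit, the called genes numbered 1822 for late INP/iOSN against INP, 1815 for Atf5 iOSN against late INP/iOSN, 3751 for Mex3a against GFP under OMP, 5348 and 2840 for Mex3a against the RING mutant under both drivers and under OMP, and 247 for the driver difference. Without a low-count filter they numbered 2025 for Atf5 iOSN, 4364 for the driver difference and 552 for the deletion, and with DESeq2 2253, 4797 and 329. With the sustentacular level as a covariate they numbered 74 and 816 for the RING mutant against GFP under both drivers and under OMP, and 685 and 1992 for Mex3a against the mutant. The driver difference numbered 3564 with the founder as a term and 1278 within founder F2 alone. Without a term per library the exonic minus intronic calls numbered 235. List tests with an estimated correlation kept 16 calls. The ratio of effective receptor numbers was 0.532 for Mex3a over GFP under both drivers, 0.726 for the RING mutant over GFP under OMP and 1.34 for Mex3a over the mutant under OMP with the inverse Simpson index, and 0.952 for Mex3a over GFP under OMP without thinning.

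Receptor genes called also moved. With the block they numbered 182 higher for INP against GBC and 251 for late INP/iOSN, and with only the compared groups 252 for late INP/iOSN. Atf5 iOSN had 42 higher and 2 lower then, 37 and 6 with DESeq2 and 35 and 10 without a filter, and mOSN 164 and 43 with DESeq2. Lower receptors of the driver difference numbered 14 with only the compared groups, 192 with DESeq2 and 252 without a filter.

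Reversed values were Inhbb at 0.58 for Mex3a under OMP and Olfr1223 at -0.88 for the RING mutant under OMP, both against wild-type mOSN, and with the covariate Hist1h2al at -0.85 for Mex3a against the mutant under OMP and Mybpc1 at -0.38 for the mutant under both drivers.

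Leaving out each library in turn gave 6944 (without GBC replicate 1) to 10019 genes for GBC against HBC, 4001 to 5031 for INP, 1505 to 2664 for late INP/iOSN, 428 to 961 for Atf5 iOSN and 2851 to 6165 for mOSN, and 7172 to 7930 for mOSN against INP in TruSeq. Mex3a against GFP gave 6177 to 8319 under both drivers and 2678 to 5674 under OMP. The RING mutant against GFP gave 3516 (without GFP replicate 1, and 3702 without RING mutant replicate 2) to 5349 under both drivers and 3959 (without RING mutant replicate 2, 4286 without replicate 1 and 4182 without GFP replicate 1) to 4883 under OMP. Mex3a against the mutant gave 5247 (without the unnumbered RING mutant library, and 5319 without Mex3a library F2) to 7656 under both drivers and 2259 (without RING mutant replicate 2, and 3315 without replicate 1) to 4599 under OMP. The driver difference ran from 318 to 4382, the deletion from 27 to 79 and the exonic minus intronic change from 929 to 7356. The ratios of receptor shares and effective numbers could hardly leave 1 SD, since that SD comes from the same libraries, so this says nothing of their stability. Under OMP without Mex3a library F1 the share ratio went from 0.135 to 0.074 against GFP and from 0.252 to 0.138 against the RING mutant.

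With replicate numbers as a block the called genes numbered 11236 for GBC against HBC (6390 higher and 4846 lower), 6837 for INP, 3338 for late INP/iOSN (1427 higher and 1911 lower), 9378 for the RING mutant under OMP and 112 for the deletion, of which 78 were among its 91. Crossed numbers gave 11628 and 10269 for GBC against HBC and for the RING mutant. Of 145 lists tested with the block, 4 changed their call: immature neuron markers in the deletion, OR choice genes in GBC against HBC (adjusted p = 0.0381 against 0.106), mRNA decay genes in INP against GBC (0.0464 against 0.0669) and red blood cell markers for the RING mutant under OMP (0.00127 against 0.452).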

Other observations

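The test of gene order and those of the splits concern patterns found in these data, and the first was chosen after its result was seen. In the TruSeq libraries GBC differed from HBC in 15184 genes, 7511 higher and 7673 lower by edgeR. Ascl1 rose by a log2 fold of 6.52 (SE 0.83, edgeR adjusted p = 7.6e-06) and Neurod1, a factor of the neuronal precursors, by 7.97, while the basal keratin Krt5 fell by 9.66 on the log2 scale. The receptor median was 1.23 there, against -3.33 in the SMARTer libraries, or -2.28 there with genes at 0 in a group set to their bound. Leaving out single libraries moved the SMARTer median between -5.97 and -2.22. Mex3b rose in both kits, with log2 folds of 3.64 and 2.27.

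The clustered protocadherin gene Pcdhb1 followed the mature neurons. It stood at 31.2 ± 4.75 CPM in Atf5 iOSN and 471 ± 93.7 in mOSN (log2 fold 3.92, SE 0.27, edgeR adjusted p = 2.2e-07), and it fell with the Mex3a transgene from 493 ± 21.1 to 43.0 ± 4.76 CPM under both drivers and from 729 ± 46.5 to 112 ± 34.0 under OMP (n = 2 each). Ribosomal protein genes fell in 56 of 85 cases from Atf5 iOSN to mOSN (camera adjusted p = 5.7e-21, adjusted p = 0.361 with an estimated correlation), and 25 of 84 were higher and 1 lower with the RING mutant under OMP (camera adjusted p = 2.6e-10, adjusted p = 0.724 with an estimated correlation). Trace amine receptors rose in 7 of 14 cases on maturation, Taar9 from 0.0710 ± 0.101 to 8.72 ± 5.52 CPM (camera adjusted p = 0.00145, adjusted p = 0.361 with an estimated correlation).

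Neighbouring receptor genes had alike cKO folds. Over 887 adjacent pairs the Spearman correlation of their folds was 0.2245, above the highest of 10000 shuffled gene orders at 0.113 (one-sided permutation p = 1e-04, the smallest they can give), which argues against a chance order. In the profiling RNA it was 0.184 in OMP cells (352 pairs, permutation p = 5e-04) and 0.168 in Ngn cells (322 pairs, permutation p = 9e-04). Differences between animals unrelated to the cKO may give the same pattern, such as linked variants around the Cre or floxed alleles. The real split was 1 of 10 splits of the 6 libraries with a correlation that high, the highest other at 0.128, and 10 splits are too few for a share under 0.05. Reads shared between paralogs, which often lie side by side, were not tested and stay open as well.

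For the 91 genes called between cKO and control, 10 splits are too few for a share under 0.05. The real split gave 91 genes and the highest of the others 3. Among the 4 splits that part as many same-numbered pairs the highest other was 2, and the remaining splits part fewer pairs.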
